A study of Triticum aestivum with 24 samples.

How the data were processed

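Flag leaves of bread wheat, Triticum aestivum, had been collected at the reproductive stage under irrigation and under drought from 4 plant materials: the drought-susceptible parent WL711, the drought-tolerant parent C306, and a susceptible and a tolerant bulk, each a pool of 10 recombinant inbred lines. Each of the 8 combinations of material and water regime had 3 arrays, labelled as replicates 1 to 3, which makes 24 Affymetrix wheat arrays. Per the labels' protocols, total RNA was isolated with TRIzol and 8 ug of it was turned into biotin-labelled cRNA. The labels do not say whether the 3 replicates came from separate plants, so the p-values measure the spread between these arrays, which may be partly technical. The duration and severity of the drought, the scan dates and any hybridisation batch are not given in the sources used here.

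The deposited values were probe set intensity on a linear scale, made with GCOS 1.2 per the submitters' processing notes. On each array the deposited intensity had a mean, after trimming 2% at each end, between 500.091 and 500.113, so the arrays had been scaled to one trimmed mean before deposit. The median signal still ran from 57.6 to 100.7 and the highest from 45694 to 163833. Detection calls were not used here, so a low value could not be separated from background, and the number of arrays limits the precision. The table held 61290 probe sets, of which 111 were array controls.

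The intensities were turned into log2(signal + 16), so a difference is on that scale and understates the change of dim probe sets. Controls were left out, together with the 40% of probe sets with the lowest mean over all arrays, which lay under a signal of 39.0, and 36707 probe sets were tested. The rule fixed before the data were examined called for centring where the medians of the arrays differed by more than 0.3. They ran from 7.83 to 8.22 over the tested probe sets, a difference of 0.387, so each array was centred on its median over those probe sets. The rule did not say over which probe sets the median should be taken, and the median over all probe sets was among the alternatives.

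The test was limma 3.58.1 in R 4.3.3: one mean for each of the 8 groups, empirical Bayes moderation with an intensity trend, 16 residual and 8.32 prior degrees of freedom, and Benjamini-Hochberg adjustment within each of the 13 comparisons at an adjusted p of 0.05. All tests were two-sided. The comparisons were drought against irrigation in each material and averaged over the 4, tolerant against susceptible in the parents and in the bulks under each regime and averaged, and the difference of the drought responses in the parents, in the bulks and averaged. A change is written as log2 ± its standard error from the fit, with 3 arrays in each group. The procedure was tried on simulated data with independent normal noise, whose spread for each probe set was pooled over the 8 groups. Of 36707 probe sets, 200 were changed on the arrays standing for drought in WL711. The procedure recovered 23 of 100 changes of log2 1 and 58 of 100 of log2 2, made 4 false calls and gave 0 changes the wrong sign. The simulation had no correlation between probe sets, no array noisier than the others and far fewer changes than were called in WL711. These rates need not hold for the real comparison.

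Genes were named from the platform annotation supplied, which gave 1273 probe sets a name, covering 771 genes, and 0 probe sets several names. The other probe sets are unnamed here. Of these genes, 770 were found in the gene table of assembly GCF_018294505.1 (IWGSC CS RefSeq v2.1), used for names alone. Only 102 had a descriptive symbol or synonym; the rest carry locus numbers beginning with LOC, for which no function is stated. In all, 948 named probe sets of 632 genes were tested. Where a gene had several probe sets, group counts used the one with the highest mean, and a change given by name is that of 1 probe set. Over the changes named by the rule described next and those called among members of the added groups, 250 were of genes with several tested probe sets. Of these, 187 had another that did not pass in the same direction, and 23 one that passed in the opposite direction.

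The genes named in the text followed a rule fixed in advance: per comparison the 5 named genes with the largest rise and the 5 with the largest fall among those called whose groups of 3 arrays did not overlap, up to 2 higher and 2 lower members of each gene list, the 5 largest positive and negative differences of response, and at most 2 unnamed probe sets in each direction. For averaged comparisons the groups had to be separate within each pair. Some genes were left out by rank. Members of the added groups described next are named outside that rule. Of 18 gene lists fixed in advance, 11 had 0 tested genes and 1 had at least 3, that of dehydrins, late embryogenesis abundant (LEA) proteins and cold-regulated proteins. A further 13 groups were therefore formed from the annotation after it was seen and before any comparison was computed, and 9 had at least 3 tested genes. They were LEA and dehydrin-type proteins, photosynthesis, redox and detoxification, starch and fructan metabolism, defence proteins, methyl cycle and methyltransferases, translation, histones and tubulins, and grain storage and inhibitor proteins. Of the other 4, chaperones and the anther tapetum had 1 tested gene each, ion transporters had 2, and gibberellin oxidases had 0.

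Lists were tested with camera at a preset correlation of 0.01. The fixed list and the added groups were adjusted as separate families, a choice made after the result with both in one family had been seen, and the p of that joint adjustment is given beside the calls. Shares of calls in the same direction carry exact binomial intervals and Fisher's exact tests across probe sets, which are not independent of one another. The drought score of an array is its mean shift, from the irrigated arrays of its own material, over probe sets that responded in the mean of the other 3 materials (adjusted p under 0.01, at least log2 1), with signs turned so that drought is positive.

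The alternatives fixed in advance were quantile normalization, centring on the median over all probe sets, pseudocounts of 1 and 64, no filter, a filter on the lowest 60%, no variance trend, array weights, a minimum change of log2 1, a fit of the compared groups alone, the replicate number as a block, each array left out in turn, and, for lists, fry and an estimated correlation. Those added after seeing the data were the values without centring, the C306 drought arrays 1 and 3 left out together, and the joint adjustment of lists. Figures were drawn with matplotlib 3.10.9.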

Results

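The flag leaf is the last leaf formed before the ear and feeds the grain. The data describe its transcripts in 2 wheat parents, WL711 (drought susceptible) and C306 (drought tolerant), and in a susceptible and a tolerant bulk of inbred lines, under irrigation and drought, with 3 arrays in each of the 8 groups. Correlations between arrays of one group ran from 0.893 to 0.973, with the lowest among the WL711 drought arrays, and 0 pairs of arrays were identical. The hybridisation spike-in signal averaged log2 13.7 ± 0.73 (SD, n = 3) on the C306 drought arrays and lay between 11.9 and 13.0 on the other arrays. C306 drought arrays 1 and 3 stood at 14.4 and 13.9, while array 2, at 12.9, lay within the range of the others. The signal of the 3' relative to the 5' probe sets ran from log2 -1.99 to 2.00 for GAPDH, from -1.90 to 2.47 for actin and from -1.58 to 2.80 for EF1a. In the susceptible bulk it was higher on each drought than on each irrigated array for GAPDH and actin, but not for EF1a. GAPDH stood at -0.53 to 0.03 there against -1.71 to -0.63 under irrigation, and actin at -0.19 to 0.39 against -1.27 to -0.26. Over these 3 controls and the 8 comparisons of 1 group with another, 24 in all, the ranges were separate in 6, among them both of these. Separate too was actin between the parents under drought (-0.32 to 0.21 in C306, 0.43 to 1.86 in WL711). For EF1a the value was higher under drought in C306 (0.42 to 1.47 against -1.19 to 0.19). It was lower under drought in the tolerant bulk (-1.36 to 0.89 against 1.42 to 2.80). Under irrigation it was higher in the tolerant than in the susceptible bulk (-0.22 to 0.42). RNA integrity was thus not shown to be equal between these groups.

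The first question was how leaves responded to drought across the 4 materials. LEA1, a late embryogenesis abundant protein of the kind that accumulates in drying tissue, rose by log2 3.77 ± 0.35 (adjusted p = 7.22e-09, 12 arrays against 12), and Rab15, a dehydrin responsive to abscisic acid, rose by 2.13 ± 0.23 (adjusted p = 9.53e-08). The fructan exohydrolases 6-FEH and 1-FEH, which release fructose from stored fructan, rose by 1.44 ± 0.13 and 0.88 ± 0.11, while AGP-S, the small subunit of the enzyme that makes ADP-glucose for starch, fell by 0.82 ± 0.12. Another 6-FEH probe set stood at -0.10 and did not pass. The xylanase inhibitor XIP-I rose by 1.95 ± 0.23, and the thaumatin-like defence protein PR5 fell by 2.17 ± 0.19 (adjusted p = 2.29e-09). Among genes known by locus number, LOC542799 rose by 4.14 ± 0.30, LOC542888 by 3.35 ± 0.26 and LOC543060 by 1.94 ± 0.12, and LOC543104 changed by -3.42 ± 0.25, LOC543329 by -2.02 ± 0.24, LOC543422 by -1.88 ± 0.12 and LOC542862 by -1.87 ± 0.20. The count was 15902 of 36707 probe sets, 7910 higher and 7992 lower.

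By group, 2 of the 3 genes of the fixed dehydrin and LEA list rose, and also 2 adjusted over the list alone, while the cold-regulated dehydrin COR410 stood at -0.10 and did not pass. The list shifted upward with camera (adjusted p = 0.0184), but adjusted p = 0.0658 with an estimated correlation and 0.0614 when adjusted jointly with the added groups. Of 7 photosynthesis genes, 5 fell and 0 rose: PsbO and PsbP of the oxygen-evolving complex (-0.78 ± 0.15, and -1.82 ± 0.20 for the more strongly changed PsbP probe set), fructose bisphosphatase FBP (-0.91 ± 0.12), PRK and the thioredoxin Trx-M. The photosynthesis group did not pass camera (adjusted p = 0.0712). Another FBP probe set stood at -0.30 and did not pass. Other members of fixed lists also had probe sets that passed: GSTZ1, a glutathione S-transferase, had 1 probe set at 0.44 ± 0.10 and another at -0.26 ± 0.10, and the plasma membrane proton pump ha1 had one at 0.54 ± 0.10. For rbcl, the large subunit of Rubisco, 1 probe set passed at 0.86 ± 0.27 and another at 0.74, while the other 15 did not pass. The call of the lower GSTZ1 probe set ended without any of 6 arrays, with adjusted p from 0.0501 to 0.0698. Without C306 drought arrays 1 and 3 its value was -0.20, that of the larger rbcl change 0.64 and that of PRK -0.29, and these calls ended. In the translation group 3 of 7 fell, led by the ribosomal protein RPL9 (-1.29 ± 0.15), and the chaperone FKBP70 fell by 1.03 ± 0.15. None of the other added groups passed camera: the adjusted p was 0.0712 for LEA and dehydrin-type proteins, 0.177 for translation, 0.395 for starch and fructan metabolism, 0.522 for grain storage and inhibitor proteins, and 0.499 for redox, defence, methyl cycle, and histones and tubulins alike. Of the 6 grain storage and inhibitor genes, markers of another tissue, 0 passed.

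In each of the 4 materials 533 probe sets were higher and 257 lower under drought, among them 18 and 21 named ones. Of the probe sets called in a pair of materials, the share that moved the same way ran from 81.1% for C306 and the tolerant bulk to 97.7% for the susceptible and tolerant bulks. RPL9 was among those lower in each, at -1.22 in WL711, -1.34 in the susceptible bulk, -1.32 in C306 and -1.27 in the tolerant bulk. Its call in WL711 ended without drought array 2 or 3 (adjusted p up to 0.0692), and in C306 without drought arrays 1 and 3 together (adjusted p = 0.448).

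**Figure D1:**
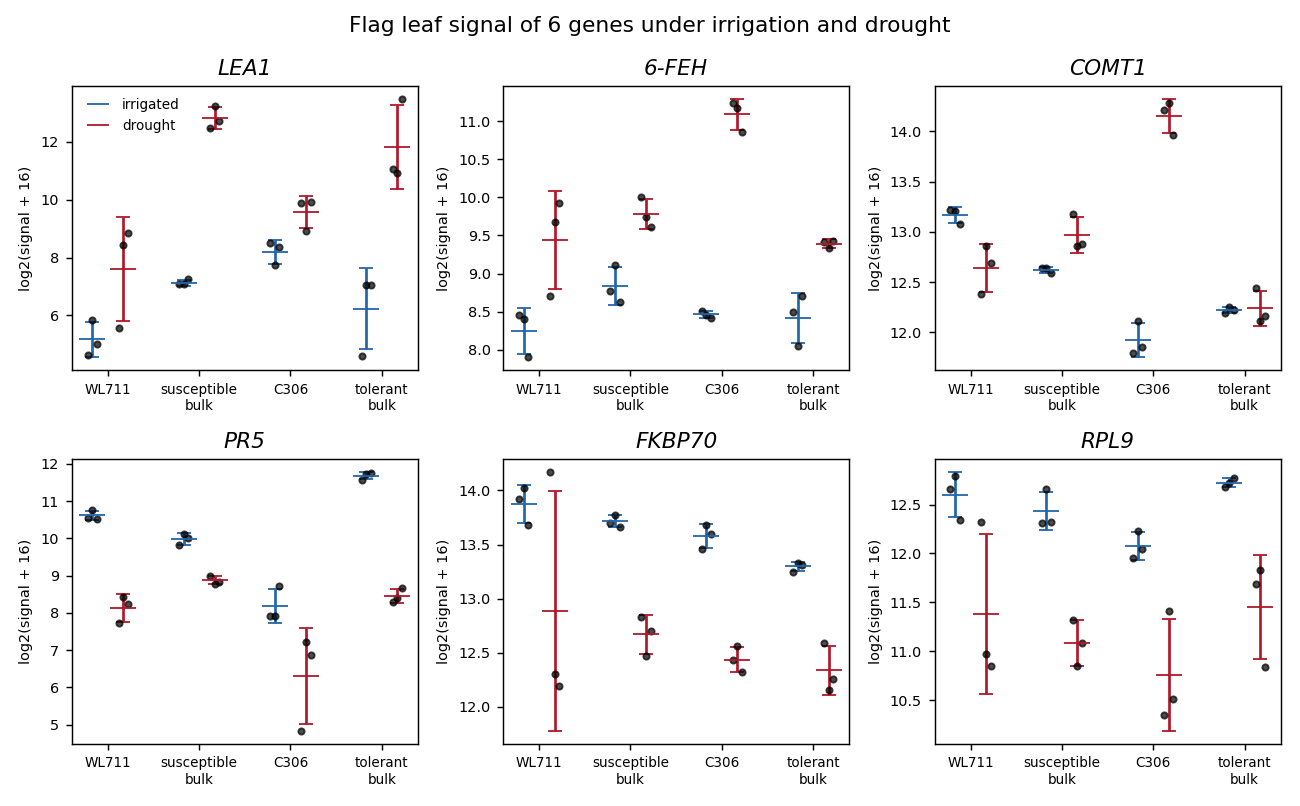
Signal of 6 genes, as log2(signal + 16) after centring, on each array (points) of 4 materials under irrigation (blue) and drought (red), with lines for the mean and bars for the SD of 3 arrays. LEA1 under drought averaged 12.8 in the susceptible bulk and 11.8 in the tolerant bulk, against 7.61 in WL711. The WL711 mean includes drought array 1, whose drought score was 0.16, against 1.22 and 1.31 for drought arrays 2 and 3.

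In WL711, drought raised LOC542799 by log2 3.67 ± 0.61 (from 6.21 ± 1.57 to 9.88 ± 1.49, SD, n = 3; adjusted p = 0.000263), LOC606323 by 3.23 ± 0.55, LOC543197 by 2.37 ± 0.52, LOC780646 by 2.19 ± 0.25 and LOC543338 by 2.11 ± 0.25. The largest fall among named genes was that of LOC100037528, by 6.08 ± 0.45, from 11.5 ± 0.08 to 5.46 ± 0.86 (SD, n = 3; adjusted p = 2.51e-08). LOC543104 changed by -4.36 ± 0.50, LOC543287 by -3.19 ± 0.64, LOC542871 by -3.07 ± 0.40 and LOC543420 by -2.77 ± 0.39. PR5 fell by 2.48 ± 0.37 and the lipid transfer protein LTP3 by 1.98 ± 0.29 (its other probe set stood at -0.19), and 6-FEH rose by 1.19 ± 0.25. The other 6-FEH probe sets stood at -0.21 and -0.26 and did not pass. PsbP fell by 1.90 ± 0.41 on 1 probe set, while the brighter one stood at -0.29 and did not pass. Of the 3 genes of the dehydrin and LEA list, LEA1 (2.44 ± 0.70) and Rab15 (1.51 ± 0.46, with its second probe set at 0.31) rose, and 3 did adjusted over the list alone; camera gave an adjusted p of 0.0247, with adjusted p = 0.0783 with an estimated correlation and 0.174 in the joint adjustment. The call of LEA1 ended without drought array 2 or 3 or irrigated array 1 or 3 (adjusted p from 0.0505 to 0.13), and that of Rab15 without drought array 2 or 3 or irrigated array 1 or 2 (0.0611 to 0.149).

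In all, 7099 probe sets changed in WL711, 3792 higher and 3307 lower, and 2131 against 3875 when arrays were centred on the median over all probe sets. Drought array 1 had a drought score of log2 0.16, near the irrigated arrays of WL711 (-0.06 to 0.07), against 1.22 and 1.31 for drought arrays 2 and 3. Without array 1 the count was 11407, without array 2 it was 3480, without array 3 it was 2986, and without irrigated array 2 it was 4489. Fitted on the 6 WL711 arrays alone, it was 717.

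**Figure D2:**
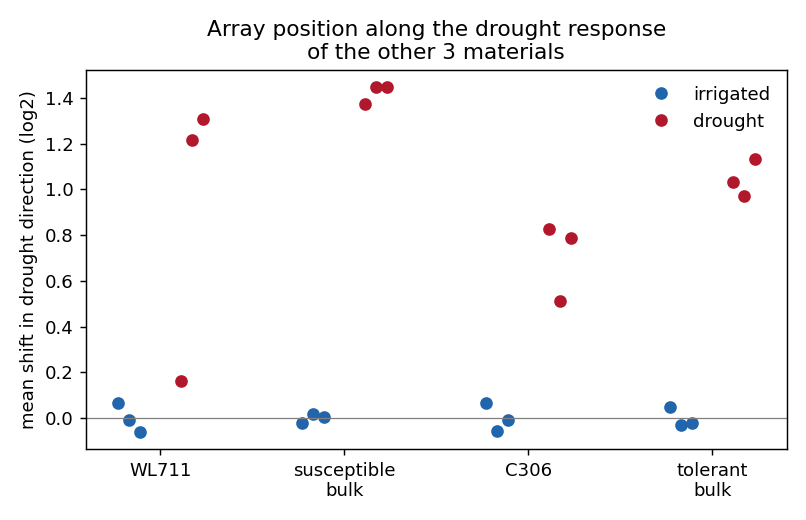
Drought score of each of the 24 arrays (points; mean log2 shift from the irrigated arrays of the same material, over probe sets that responded in the other 3 materials) by material, with irrigated arrays in blue and drought arrays in red. Irrigated arrays lay between -0.06 and 0.07; drought array 1 of WL711 was at 0.16, and the other drought arrays were between 0.51 and 1.45.

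The susceptible bulk carried the largest drought rise among named genes, that of LOC100037518 by log2 8.33 ± 0.46, from 5.70 ± 0.58 to 14.03 ± 0.19 (SD, n = 3; adjusted p = 6.94e-12). LOC606323 rose by 6.83 ± 0.55, LOC542799 by 6.15 ± 0.61, LOC100125738 by 5.85 ± 0.58 and LEA1 by 5.69 ± 0.70 (adjusted p = 1.3e-06). XIP-I rose by 3.90 ± 0.41 and Rab15 by 3.85 ± 0.46. Lower under drought were LOC542989 (-4.99 ± 0.96), LOC543104 (-4.36 ± 0.50), LOC543256 (-3.38 ± 0.40), LOC100125715 (-2.32 ± 0.38), PsbP (-2.27 ± 0.41, with the brighter probe set at -0.65 and not passing), RPL9 (-1.34 ± 0.30), FBP (-1.06 ± 0.25) and AGP-S (-1.05 ± 0.23). Another FBP probe set stood at 0.03 and did not pass. The dehydrin and LEA list had 2 of 3 genes higher, 2 also adjusted over the list alone, and camera gave an adjusted p of 0.00614, with adjusted p = 0.0356 with an estimated correlation and 0.0336 in the joint adjustment. A total of 8774 probe sets changed, 4676 higher and 4098 lower, against 4161 and 5776 without centring, and the 3 drought arrays had scores of 1.38, 1.45 and 1.45.

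C306 responded with a rise of LOC542773 by log2 4.28 ± 0.43 (from 8.58 ± 0.33 to 12.9 ± 0.87, SD, n = 3; adjusted p = 1.01e-07), LOC780687 by 3.78 ± 0.21, LOC542888 by 3.65 ± 0.52, LOC542774 by 3.64 ± 0.35 and LOC100037637 by 3.11 ± 0.52. The enzyme COMT1, a methyltransferase of lignin synthesis, rose by 2.23 ± 0.15, 6-FEH by 2.63 ± 0.25 and the beta-tubulin tubb1 by 1.74 ± 0.19. Another 6-FEH probe set was called lower, at -1.52. Among the lower genes were LOC542989 (-4.54 ± 0.96), LOC543127 (-3.49 ± 0.45), LOC543317 (-3.46 ± 0.36), the histone wcH2B-6 (-3.13 ± 0.57), LOC100125715 (-2.65 ± 0.38), PR5 (-1.88 ± 0.37), AGP-S (-1.45 ± 0.23) and PsbO (-1.26 ± 0.30). None of the 3 dehydrin and LEA genes passed on the probe set used for the list, LEA1 standing at 1.37 and Rab15 at 0.88, and 0 did adjusted over the list alone; camera gave an adjusted p of 0.375. A second Rab15 probe set rose by 2.75 ± 0.52.

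The count in C306 was 7748, 3368 higher and 4380 lower, against 1997 and 6109 when centred on the median over all probe sets, which moved the median change to log2 -0.23. C306 drought arrays 1 and 3 had the high spike-in signals given above, against 12.4 ± 0.15 (SD, n = 3) on the irrigated ones. The count was 4933 without drought array 1 and 5004 without array 3. A further fit left out both. In that last fit, where the 1 drought array left was assumed to vary like the other groups, the calls of PsbO (adjusted p = 0.473), PR5 (0.0834), LOC542989 (0.452), LOC542888 (0.0531) and wcH2B-6 (0.0638) ended.

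In the tolerant bulk LEA1 rose by log2 5.59 ± 0.70, from 6.23 ± 1.40 to 11.8 ± 1.44 (SD, n = 3; adjusted p = 4.9e-06). LOC606323 rose by 5.47 ± 0.55, LOC542799 by 5.09 ± 0.61, LOC542888 by 3.54 ± 0.52, LOC543479 by 3.36 ± 0.68, Rab15 by 2.27 ± 0.46, XIP-I by 1.79 ± 0.41 and 1-FEH by 1.30 ± 0.22. LOC542773 changed by -5.06 ± 0.43 and LOC542774 by -3.30 ± 0.35, both of which rose in C306, and LOC542989 by -4.47 ± 0.96, LOC100037528 by -3.86 ± 0.45 and LOC543422 by -3.54 ± 0.22. PR5 fell by 3.22 ± 0.37, and PsbP by 2.56 ± 0.41 on its dimmer probe set. PsbO fell by 1.19 ± 0.30, a call that ended under quantile normalization (adjusted p = 0.116). Again the dehydrin and LEA list had 2 of 3 genes higher, 2 also adjusted over the list alone, with a camera adjusted p of 0.0278, adjusted p = 0.084 with an estimated correlation and 0.104 in the joint adjustment. Of the 7 photosynthesis genes 3 fell (PsbO, PRK and FBP), PsbP being counted there by its brighter probe set, which stood at -0.84 and did not pass. The group shifted downward with camera (adjusted p = 0.00205; 0.00228 in the joint adjustment), but with adjusted p = 0.248 with an estimated correlation. The call of PRK ended without drought array 3 or any 1 irrigated array (adjusted p from 0.0537 to 0.182). The count was 6836, 4051 higher and 2785 lower, and 5250 against 1458 when centred on the median over all probe sets, which moved the median change to 0.17.

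The next question was how the tolerant and susceptible parents differed at one water regime. Under irrigation LOC543418 was higher in C306 than in WL711 by log2 6.98 ± 0.85 (12.2 ± 0.03 against 5.26 ± 0.59, SD, n = 3; adjusted p = 1.65e-06; its other probe set stood at -0.59 and did not pass), LOC543111 by 5.02 ± 0.65, LOC100037571 by 4.36 ± 0.35, LOC543197 by 4.30 ± 0.52 and LOC542898 by 3.89 ± 0.24. Another LOC543111 probe set stood at 0.15 and did not pass. LEA1 (3.03 ± 0.70, adjusted p = 0.00344), XIP-I (2.82 ± 0.41), Rab15 (1.85 ± 0.46, with its second probe set at -0.55) and PEAMT1, which makes the choline precursor phosphocholine (1.18 ± 0.23), were also higher in irrigated C306. Lower there were LOC100037528 (-6.92 ± 0.45), LOC543104 (-4.55 ± 0.50), LOC543287 (-4.08 ± 0.64), LOC542772 (-3.54 ± 0.37), LOC100037541 (-2.97 ± 0.37), PR5 (-2.43 ± 0.37), LTP3 (-2.14 ± 0.29, the other probe set at 0.54 and not passing) and COMT1 (-1.24 ± 0.15). The dehydrin and LEA list had 2 of 3 genes higher, 2 also adjusted over the list alone, with a camera adjusted p of 0.0189, adjusted p = 0.0669 with an estimated correlation and 0.135 in the joint adjustment. The count was 5893, 3022 higher and 2871 lower in C306, against 1687 and 3499 when centred on the median over all probe sets, and 3853 without irrigated array 2 of WL711.

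Under drought LOC543418 was again higher in C306 on the same probe set, by 5.49 ± 0.85 (the other stood at -0.69 and did not pass), as were LOC542773 (5.35 ± 0.43; 12.9 ± 0.87 against 7.51 ± 0.84, SD, n = 3; adjusted p = 1.34e-09), LOC100037571 (5.001 ± 0.35), LOC542774 (4.02 ± 0.35) and LOC780602 (3.87 ± 0.39, its other 4 probe sets lying between -0.65 and 1.52 and not passing). 6-FEH and COMT1 were higher by 1.65 ± 0.25 and 1.51 ± 0.15. Another 6-FEH probe set stood at -0.74 and did not pass. Lower in C306 were LOC543383 (-2.32 ± 0.50), LOC606310 (-2.0004 ± 0.37), LOC542901 (-1.97 ± 0.30, with another probe set higher by 0.82), LOC543390 (-1.91 ± 0.39), PR5 (-1.82 ± 0.37) and AGP-S (-1.22 ± 0.23). Another LOC606310 probe set stood at -0.11 and did not pass. Of the dehydrin and LEA list 0 of 3 genes passed, and 2 were higher adjusted over the list alone, with a camera adjusted p of 0.248. The second Rab15 probe set was higher in C306 by 1.89 ± 0.52 (adjusted p = 0.0153), a call that ended without C306 drought array 3 or WL711 drought array 2 or 3 (0.0549 to 0.0717) and without C306 drought arrays 1 and 3 (0.122). The count was 5153, 1968 higher and 3185 lower, against 1101 and 4968 when centred on the median over all probe sets, which moved the median difference to log2 -0.25. It was 3052 without C306 drought array 1, 3166 without array 3, 1159 without both, and 864 in a fit of these 2 groups alone. Without both arrays the calls of LOC543383 (adjusted p = 0.293), LOC606310 (0.442), LOC543390 (0.0648) and PR5 (0.137) ended. The spike-in signal was 13.7 ± 0.73 (SD, n = 3) on the C306 and 12.6 ± 0.46 on the WL711 drought arrays. Of the 1704 probe sets called between the parents under both regimes, 84.2% differed in the same direction.

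The bulks, each a pool of 10 lines sorted by drought tolerance, addressed the same question in pooled lines. With 1 parent or 1 pool on each side, the p-values measure the spread between arrays and not between genotypes. A link to tolerance cannot be told apart from other differences between these parents or pools. Under irrigation LOC543317 was higher in the tolerant bulk by log2 2.72 ± 0.36 (12.4 ± 0.27 against 9.68 ± 0.16, SD, n = 3; adjusted p = 3.16e-05), LOC542839 by 2.58 ± 0.29, LOC100037528 by 2.51 ± 0.45, LOC543492 by 2.24 ± 0.20 and PR5 by 1.69 ± 0.37. Lower were LOC543018 (-2.38 ± 0.47), LOC100037600 (-2.22 ± 0.49), LOC542771 (-1.92 ± 0.31), LOC780686 (-1.83 ± 0.40), 1 LTP3 probe set (-1.74 ± 0.32, with another at 0.82 that did not pass) and GSTZ1 (-1.01 ± 0.20, with a further probe set at 0.31 that did not pass). For LOC542771, 2 further probe sets stood at -0.22 and -0.36 and did not pass. Of the 7 photosynthesis genes 4 were higher, namely PsbO (1.40 ± 0.30), rbcl (1.39 ± 0.33), the Rieske protein petC (1.24 ± 0.29) and PRK (0.74), and the group passed camera (adjusted p = 0.000885; 0.000983 in the joint adjustment), but with adjusted p = 0.335 with an estimated correlation. Of the other 16 rbcl probe sets 9 did not pass. Under quantile normalization the calls of PsbO (adjusted p = 0.263), rbcl (0.869) and petC (0.0935) ended and PRK turned to -0.23. PRK also lost its call without 5 of the 6 arrays (adjusted p from 0.0541 to 0.111), the exception being array 2 of the susceptible bulk. In the dehydrin and LEA list 0 genes passed, 0 also adjusted over the list alone. The count was 5165, 2361 higher and 2804 lower, against 769 and 6085 when centred on the median over all probe sets, which moved the median difference to -0.30. It was 2917 without array 1 and 3075 without array 3 of the susceptible bulk, and 3399 without array 2 of the tolerant bulk.

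Under drought LOC100037518 was lower in the tolerant than in the susceptible bulk, with a difference of log2 -5.41 ± 0.46 (8.62 ± 0.23 against 14.03 ± 0.19, SD, n = 3; adjusted p = 4.72e-08), and so were LOC606307 (-4.04 ± 0.53), LOC542887 (-4.03 ± 0.49), LOC542774 (-4.02 ± 0.35) and LOC542773 (-4.01 ± 0.43). AGP-S was higher by 1.17 ± 0.23 (adjusted p = 0.00287), LOC606363 by 1.18 ± 0.20 and LOC543463 by 1.16 ± 0.25 (2 of its other probe sets, at -0.30 and -0.13, did not pass). From the dehydrin and LEA list 0 of 3 genes passed, with 1 lower adjusted over the list alone. Of the 7 photosynthesis genes 0 passed, although the group did with camera (adjusted p = 0.0477), with adjusted p = 0.571 with an estimated correlation and 0.053 in the joint adjustment. Under quantile normalization 0 of the 3 photosynthesis shifts passed. The count was 2205, 914 higher and 1291 lower, against 1451 and 1359 without centring and 383 and 1460 when centred on the median over all probe sets. It fell to 1384, 1110 and 990 without drought arrays 1, 2 and 3 of the susceptible bulk, and was 1002, 913 and 4776 without those of the tolerant bulk.

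Averaged over parents and bulks and both regimes, 2 named genes higher in the tolerant materials met the rule, LOC100037560 (log2 1.25 ± 0.08, adjusted p = 2.95e-11) and LOC542837 (1.19 ± 0.11), and 1 lower, LOC542901 (-1.24 ± 0.15), whose other 2 probe sets were called higher (0.45 and 0.46). PEAMT1 was higher by 0.72 ± 0.11, and 1 rbcl probe set by 0.92 ± 0.18 (adjusted p = 0.000908). Of the other 16 rbcl probe sets 12 did not pass, and the rest were called higher too, among them 1 at 0.87. The dehydrin and LEA list had 0 of 3 genes called, 0 also adjusted over the list alone, with a camera adjusted p of 0.109. The count was 4867, 2189 higher and 2678 lower, but 817 and 7246 when centred on the median over all probe sets, which moved the median difference to -0.19.

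Parents and bulks differed in opposite directions more often than in the same one under irrigation, while under drought the share in the same direction depended on the processing. Under irrigation 1383 probe sets were called in both comparisons, of which 356 differed in the same direction (25.7%, 95% interval 23.5 to 28.1; Fisher's exact p = 1.19e-74). The 198 higher in both tolerant materials were near the 194 that independent lists would share and the 158 lower were under the 219, whereas 1027 ran in opposite directions against 416. Under drought the same-direction share was 33.4% of 605 (29.6 to 37.3; Fisher's exact p = 6.26e-19). PR5, LOC100037528 and LOC542773 were among the genes with opposite signs, PR5 and LOC100037528 under irrigation and LOC542773 under drought. Under drought 246 ran alike and 276 in opposite directions (47.1%) when centred on the median over all probe sets, and 186 and 189 (49.6%) without a filter. With centring over all probe sets most calls were lower on both sides, 4968 against 1101 for the parents and 1460 against 383 for the bulks. Independent lists would then agree more often than not, so an even split is not the reference for that 47.1%. The share under drought was 45.1% without WL711 drought array 1 and 25.8% without array 3, and 40.1% and 27.8% without drought arrays 2 and 3 of the tolerant bulk. Only 26 probe sets, 9 higher and 17 lower in the tolerant material, were called alike in all 4 comparisons, against 14.5 for independent lists, and 0 of them were named. A further 75, against 14.6, ran in opposite directions in parents and bulks under both regimes.

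**Figure D3:**
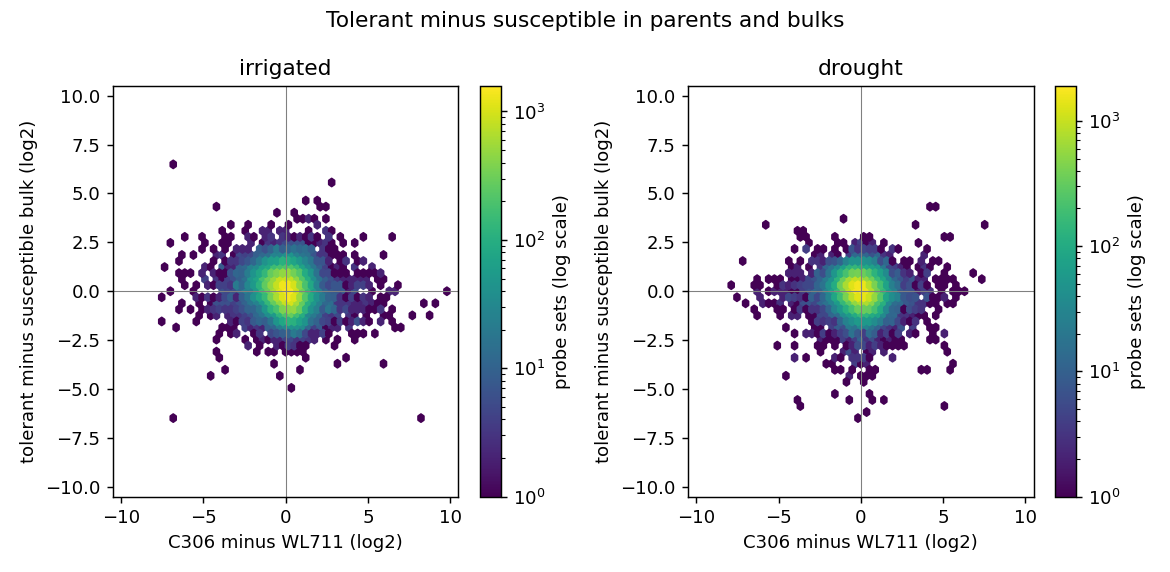
Difference between C306 and WL711 (horizontal axis, log2) against that between the tolerant and susceptible bulk (vertical axis, log2) over 36707 probe sets, under irrigation and under drought, with the number of probe sets in each hexagon as colour on a log scale. The correlation across probe sets was -0.13 under irrigation and -0.10 under drought.

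The last question was whether the drought response itself differed between tolerant and susceptible materials. Between the parents, LOC542773 responded more positively in C306 than in WL711 by log2 6.88 ± 0.60 (adjusted p = 2.13e-08), LOC100037528 by 6.15 ± 0.63, LOC542774 by 5.63 ± 0.50, LOC780687 by 4.96 ± 0.30 and LOC780599 by 4.58 ± 0.43. LTP3, which fell in WL711 and stood at 0.78 in C306, differed by 2.76 (0.49 on the other probe set, not passing), and COMT1, which rose in C306, by 2.75. More negative in C306 were the responses of LOC543197 (by -4.21 ± 0.74; 2.37 in WL711 and -1.84 in C306), LOC606323 (-3.71 ± 0.78; 3.23 and -0.48) and LOC543127 (-3.16 ± 0.64; -0.33 and -3.49). The last call ended without C306 drought arrays 1 and 3 (adjusted p = 0.103). The count was 2841, 1133 higher and 1708 lower, but 4783 without WL711 drought array 1 and 1314 without C306 drought arrays 1 and 3.

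Between the bulks LOC100037518 rose by less in the tolerant bulk (1.62 against 8.33, a difference of log2 -6.70 ± 0.66, adjusted p = 1.25e-06), as did LOC100125738 (-4.83 ± 0.82; 1.02 against 5.85) and LOC606307 (-4.34 ± 0.75; 0.20 against 4.54). LOC542773 fell there (-4.57 ± 0.60; -5.06 against -0.48), and LOC100125744 responded more positively by 1.28 ± 0.22 (0.47 against -0.81). The difference for LEA1, -0.10, did not pass. The count was 959, 323 higher and 636 lower, against 659 and 666 without centring, 672 and 724 under quantile normalization, and 572 and 354 when centred on the median over all probe sets, where the median difference was 0.27. Leaving out array 1 or 3 of the irrigated susceptible bulk gave 548 and 609, and leaving out drought array 1, 2 or 3 of that bulk gave 563, 616 and 556.

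Averaged over parents and bulks, the difference of response was positive for LOC780599 (2.25 ± 0.30, adjusted p = 4.05e-05), LOC100037528 (2.09 ± 0.45) and LOC780687 (1.49 ± 0.21), but it came from the parents. In the bulks these genes stood at -0.07, -1.96 and -1.99, of which the last was called (adjusted p = 0.00033). The average was negative for LOC100037518 (-4.11 ± 0.46), LOC543197 (-3.88 ± 0.52), LOC606307 (-2.86 ± 0.53), LOC100125738 (-2.62 ± 0.58) and XIP-I (-1.96). Between the parents the differences of LOC100037518 (-1.52), LOC606307 (-1.39), LOC100125738 (-0.41) and XIP-I (-1.81) did not pass, nor did that of XIP-I between the bulks (-2.11). The dehydrin and LEA list had 0 of 3 genes called in each of the 3 comparisons of response on the probe sets used for it, 0 also adjusted over the list alone, with camera adjusted p of 0.226 for the parents, 0.197 for the bulks and 0.0702 averaged. The second Rab15 probe set did pass, its response being larger in C306 than in WL711 by 2.44 ± 0.73 (adjusted p = 0.04) and smaller in the tolerant than in the susceptible bulk (-2.66 ± 0.73, adjusted p = 0.0498). Both calls were near the threshold and ended without any 1 of 8 and of 10 arrays (adjusted p up to 0.136 in each). The count was 1445, 484 higher and 961 lower, against 877 and 909 without centring, 849 and 990 under quantile normalization, 485 and 529 when centred on the median over all probe sets, and 3328 without WL711 drought array 1.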

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

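Chosen only after the result was seen were the tests of foreign RNA, of a label swap and of a dim array for WL711, the comparison against pairs of irrigated arrays, the tests of scaling and of parental alleles, and both tests on rbcl.

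The drought response differed between tolerant and susceptible material, by a test of that difference, for 2841 probe sets in the parents, 959 in the bulks and 1445 on average. The genes listed here are the largest named differences by the rule and called members of the gene lists and added groups. Other named genes were called too, among them LOC542871 in the parents (3.81) and LOC542774 in the bulks (-4.21). In the parents the listed genes with a more positive log2 response in C306 were LOC542773 (6.88), LOC100037528 (6.15), LOC542774 (5.63), LOC780687 (4.96), LOC780599 (4.58), LTP3 (2.76), COMT1 (2.75), a second Rab15 probe set (2.44), tubb1 (1.85), tubb2 (1.59), 6-FEH (1.44, with another probe set at -1.26 that did not pass) and TEF1 (0.92). Those with a more negative one were 2 rbcl probe sets (-4.58 and -3.25), LOC543197 (-4.21), LOC606323 (-3.71), LOC543127 (-3.16), wcH2B-6 (-2.83), PCS1 (-1.64), GSTZ1 (-1.27), ALP (-0.91), Eif4B (-0.81) and TPC1 (-0.80). The calls of the first rbcl probe set, wcH2B-6, Eif4B, TPC1, TEF1 and Rab15 ended when 1 of several arrays was left out, with adjusted p up to 0.11, 0.0982, 0.0892, 0.113, 0.0852 and 0.136, and that of ALP without C306 drought array 3 (0.0517). Without C306 drought arrays 1 and 3, those of GSTZ1 (adjusted p = 0.155), PCS1 (0.259), 6-FEH (0.0629), LOC543127 (0.103) and the other rbcl probe set (0.0784) ended too, and those 7 as well (Rab15, 0.0989). In that fit, with fewer arrays, the differences of 6-FEH (1.53), TEF1 (0.96) and Rab15 (2.76) had not shrunk, while those of the others had (GSTZ1 to -0.92, PCS1 to -1.03, LOC543127 to -2.08). TEF1 and Eif4B are translation factors, PCS1 makes phytochelatin and TPC1 is a vacuolar cation channel.

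In the bulks the response was more positive in the tolerant one for LOC542856 (1.74), LOC100125744 (1.28), LOC543378 (1.22), LOC606324 (1.204) and LOC606332 (1.15), and more negative for LOC100037518 (-6.70), rbcl (-5.24 and -3.02), LOC100125738 (-4.83), LOC542773 (-4.57), LOC606307 (-4.34), the second Rab15 probe set (-2.66) and PR5 (-2.11). Leaving out 1 array ended the calls of LOC542856 (adjusted p = 0.051), LOC543378 (up to 0.0614), LOC606324 (0.0602), LOC606332 (0.108), PR5 (0.08), Rab15 (0.136) and the first rbcl probe set (0.0912). Averaged over parents and bulks the values were 2.25 for LOC780599, 2.09 for LOC100037528, 1.89 for LOC543104, 1.57 for LOC542871, 1.49 for LOC780687, 1.21 for COMT1 and 1.07 for LTP3, and -4.91 and -3.14 for rbcl, -4.11 for LOC100037518, -3.88 for LOC543197, -2.86 for LOC606307, -2.62 for LOC100125738 and -1.96 for XIP-I. Of the 7 positive averages listed here, 6 came from the parents, the bulk difference being under 0, and that of LOC780687 was called (-1.99). LOC543104 (1.11 in the bulks) was the other. Here LOC543104 and LTP3 lost their calls without 1 of several arrays (adjusted p up to 0.0615 and 0.0662), and LOC542871 and LTP3 without C306 drought arrays 1 and 3 (0.0884 and 0.171).

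Whether other groupings of the arrays call as many probe sets was counted for each comparison. For the mean drought response only the real split of 100 called as many (15902 calls against at most 2919 in another split). The same held for the mean tolerant against susceptible difference (1 of 100, 4867 against 2311). Both shares speak against chance in how these arrays were grouped. They do not cover chance differences between single genotypes or pools. For the mean difference of response the share was 2 of 100, but another split called more (1459 against 1445). Its splits also exchange materials within a regime, so they do not exclude chance. Nor was chance excluded for the difference of response between the parents (6 of 100, 2841 against 8090) or between the bulks (7 of 100, 959 against 6710). Splits with several times the real count point to a structure of the samples: exchanging the materials within 1 water regime turns the difference between materials into one of response. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05; the real one ranked highest (1 of 10) in each. The real count and the highest other were 7099 and 1484 for drought in WL711, 8774 and 0 in the susceptible bulk, 7748 and 8 in C306, 6836 and 13 in the tolerant bulk, 5893 and 1 for the irrigated parents, 5153 and 1577 for the parents under drought, 5165 and 0 for the irrigated bulks, and 2205 and 1612 for the bulks under drought.

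Drought array 1 of WL711 lay near the irrigated arrays on the drought response. A swap with an irrigated WL711 array was excluded, because the highest drought score among those was 0.067, and so was a dim array, its spike-in signal of 12.1 lying within the 11.9 to 13.0 of arrays outside C306 under drought. An irrigated WL711 leaf under a drought label stays open: 723 probe sets separated the array from the 3 irrigated ones, above the bound of 5 times the 112 of a single irrigated array set beforehand, but that bound was unfair since a single irrigated array has 2 references, and against pairs of irrigated arrays the count was 556 to 589, on both sides of it. The 112 was the highest value among the single irrigated arrays, not a typical one. Drought array 1 was assumed there to vary like the other groups. Of the 472 of those 723 that responded to drought in the other materials, 257 moved in the drought direction and 215 against it, which for 1 array and probe sets that are not independent decides nothing. RNA of another material cannot be told apart either: at markers chosen without the array its median position between WL711 (0) and C306 (1) was 0.128, the other WL711 drought arrays lying at 0.024 and 0.004 and the lowest array of the other 3 materials at 0.431, which argues against a whole replacement and leaves a partial mixture. A leaf that had not yet met the drought may also be the source, which was not tested.

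Tolerant and susceptible material differed in opposite directions in parents and bulks, under drought less firmly, as the same-direction share was 49.6% there without a filter. Scaling was excluded as the whole cause under irrigation, since the share of same-direction calls reached at most 39.5% (36.8 to 42.2) in 3 other scalings. Under drought the test cannot decide. Centring on the median over all probe sets gave 47.1% (42.8 to 51.5), whereas the other 2 scalings gave 28.6% and 27.0%. The test set the share against an even split. With that centring most calls were lower in both comparisons, so independent lists would agree more often than that. For opposite parental alleles in the bulks, 372 markers with parental differences of at least log2 2 were used. Of their bulk differences, called or not, 47.6% (42.4 to 52.8) had the parental sign. Of those called in the bulks under both regimes 18 had it and 21 had not. These markers thus showed no clear excess of either sign. The interval holds 50%, so the test cannot decide on opposite alleles there. The 25.7% alike under irrigation is a share among calls at 1 regime and is not directly comparable. Smaller parental differences were not covered, so the explanation stays open for them too. For a different position of the leaves along the drought response, probe sets without a mean drought response (unadjusted p above 0.5) were used. Under irrigation their same-direction share was still 28.5% (21.4 to 36.4, 43 alike and 108 opposite), under the bound set beforehand for excluding it as the whole cause. That exclusion is not firm, because responses that cancel between materials also give a small mean. Such a position stays open, also as part of the cause. The irrigated parental difference correlated with the mean drought response at 0.26 and the irrigated bulk difference at -0.12. Parents and bulks correlated at -0.06 among probe sets without that response against -0.20 among those with it. Under drought the share was 49.1% (35.4 to 62.9), which leaves that explanation open there. A difference in how the genotypes stood in development or water status may remain, and was not tested.

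A pair of rbcl probe sets (differences of -5.24 and -3.02 between the bulks) differed in drought response between tolerant and susceptible material. Both were called higher in the susceptible bulk (3.27 and 2.23) and lower in C306 (-2.77 and -1.60), and the second was higher in WL711 (1.65). The rise of the first in WL711 (1.81) and the falls in the tolerant bulk (-1.97 and -0.78) did not pass. Of those calls, that of the first ended in the susceptible bulk without drought array 2 or irrigated array 1 (adjusted p up to 0.0619) and in C306 without drought array 1 or 3 or irrigated array 2 or 3 (up to 0.196), and that of the second in C306 without drought array 1 or 3 (0.0648) and in WL711 without drought array 2 or 3 (0.0881). Whether C306 drought arrays 1 and 3, which have high spike-in signals, made the difference between the parents cannot be told apart: without them it went from -4.58 ± 1.35 to -2.05 ± 1.47 and from -3.25 ± 0.62 to -2.41 ± 0.74, and both calls ended (adjusted p = 0.554 and 0.0784), as the differences shrank and 1 C306 drought array was left. The bulks hold no C306 array, so their differences do not test it. A change of rbcl transcript as a whole cannot be told apart from one of these probe sets: the other 15 had a median difference of -0.57, with quartiles of -1.47 and -0.16, in the same direction and smaller, and 1 of them was called as well (-2.19 in the parents, -2.69 in the bulks). A difference in rbcl expression between the materials stays among the open explanations, as untested.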

How the results depend on the processing

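The values without centring, the fit without C306 drought arrays 1 and 3 and the joint adjustment of lists were chosen after seeing the data.

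Each setting lists here the counts it moved by over 1.5 times and the same-direction shares it moved beyond their interval. Quantile normalization gave shares of 28.5% under irrigation and 28.6% under drought. Centring on the median over all probe sets gave 8063 for tolerant against susceptible on average and shares of 39.5% and 47.1%. No filter gave 1893 for the parental difference of response, 876 for the averaged one, and shares of 37.8% and 49.6%; leaving out the lowest 60% gave 1500 for the difference between bulks in response and 26.4% under drought. Array weights gave 16969 for drought in WL711, 17686 in the susceptible bulk, 12654 for irrigated parents, 8777 and 9298 for bulks under irrigation and drought, 9483 for the mean difference, and 7496, 3388 and 5382 for the differences of response in parents, bulks and on average. A minimum change of log2 1 gave, by its construction, 4138, 5523, 4703 and 4027 for drought in WL711, the susceptible bulk, C306 and the tolerant bulk, 3476 on average, 3750 and 3046 for the parents, 2893 and 1325 for the bulks, 861 on average, 963 for the averaged response, and shares of 29.6% and 40.5%. A fit of the compared groups alone, with fewer arrays, gave 717 for WL711, 13970 for the susceptible bulk, 10708 and 864 for the parents, 8496 for irrigated bulks, 1683 and 1591 for the differences of response, and 29.7% and 43.7%. No centring gave 27.0% under drought. Without C306 drought arrays 1 and 3 the counts were 1655 for C306, 1159 for parents under drought and 1314 for their response, and the share 43.8%. Of 5 shifts of the fixed list by camera, 1 held with an estimated correlation and 1 in the joint adjustment, and fry called 8. Of 3 shifts of an added group, all of photosynthesis, 0 and 2 held; among the added groups fry called 34, quantile normalization gave 0 and no filter 6. Apart from the stated constructions, the cause was not tested.

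With 1 array left out, counts ran from 2986 to 11407 for WL711, 6581 to 7135 for the susceptible bulk, 4933 to 9157 for C306, 5187 to 6192 for the tolerant bulk and 14729 to 17620 on average. They ran from 3853 to 4570 and 3052 to 7073 for the parents under irrigation and drought, 2917 to 4219 and 913 to 4776 for the bulks, 3920 to 6229 on average, and 1971 to 4783, 548 to 1027 and 1017 to 3328 for the differences of response. Shares ran from 23.1% to 28.4% under irrigation and 25.8% to 45.1% under drought. The lowest and highest came without drought arrays 3 and 1 for WL711, without C306 drought arrays 1 and 2 for C306 and for the parents under drought, and without drought arrays 2 and 3 of the tolerant bulk for the bulks under drought; the highest differences of response in the parents and on average came without WL711 drought array 1.

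Signs reversed only under quantile normalization: PRK to -0.23 between irrigated bulks and -0.10 on average, SAHH to -0.0034 on average, and TCTP to -0.036 between irrigated bulks. These 4 results did not pass there either, and they are not among the 25 ended calls counted next for that setting. Of 346 single-gene results, calls ended for 116 with a minimum change of log2 1, 71 (of 269 it applied to) in a fit of the compared groups alone, 64 without a filter, 60 (of 156) without C306 drought arrays 1 and 3, 47 centred on the median over all probe sets, 37 without a trend, 25 under quantile normalization, 12 (of 343) with a pseudocount of 1, 7 without centring, 4 with array weights, 4 (of 318) without the lowest 60% and 1 with a pseudocount of 64. The median change moved past 0.1 also to -0.102 for the susceptible bulk centred over all probe sets and to -0.12 without centring, and to 0.12 for the bulks' response without centring and under quantile normalization; that of the parental response went from -0.107 to -0.16 centred over all probe sets. Same-numbered arrays did not deviate together (correlations from -0.14 to 0.19), so the numbers do not pair them; with the replicate block the counts stayed within 1.5 times (7135 for WL711), and 2 single-gene calls ended, H2A-2 on average (adjusted p = 0.0598) and TPC1 in C306 (0.0545). Signal near background limits dim probe sets, as no detection calls were used.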

Other observations

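Members of the added groups that the account by comparison left out also moved. The examples were chosen after their values were seen. Under drought lgul, a lactoylglutathione lyase of detoxification, changed by log2 -0.82 in the susceptible and -0.93 in the tolerant bulk. The call of lgul in the susceptible bulk ended without irrigated array 2 (adjusted p = 0.0609). PCS1, which makes phytochelatin from glutathione, rose by 1.13 in WL711 and by 1.04 in the tolerant bulk, where the call ended without irrigated array 1 (adjusted p = 0.113). PIMT, a protein repair methyltransferase, was lower in C306 than in WL711 under drought (-1.29), a call that ended without C306 drought arrays 1 and 3 (adjusted p = 0.307).

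Among cytoskeletal and chromatin genes, the beta-tubulin tubb1 rose by 1.07 in the susceptible bulk, whereas tubb3 changed by -0.95 in the tolerant bulk. The histone H2A-3 was lower in the tolerant than in the susceptible bulk under irrigation by -1.10. The group as a whole had 3 genes higher and 4 lower in the mean drought response and did not pass camera (adjusted p = 0.499).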
